A study of Homo sapiens with 4 samples.

How the data were processed

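RNA was measured in A549 and HCC827 cells, 2 established human lung adenocarcinoma lines, after 24 h with DMSO or with 20 µM hinokitiol. Hinokitiol is a tropolone-type natural compound that binds iron and other metals. Each of the 4 groups held 1 library. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, the second strand was marked with dUTP and removed before amplification, the adapters carried unique molecular identifiers, and libraries were read as 150-base pairs. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, UMI-tools, StringTie 1.3.4d, DESeq2 and edgeR without their order or role. Whether reads were collapsed by molecular identifier, and whether counting used strand, is not given in the sources used here. The same notes name the mouse build GRCm39, although all 60612 identifiers in the count table are human Ensembl genes, so no coordinates are given.

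The authors deposited a table of estimated counts per gene and a table of FPKM values. The deposited estimated counts are whole numbers with library totals of 74591473 (A549 with DMSO), 75099948 (A549 with hinokitiol), 74688034 (HCC827 with DMSO) and 72146216 (HCC827 with hinokitiol). Among genes with 3 to 42 counts, between 35.6% and 36.5% of the values in a library were multiples of 4, against 25% by chance. A fragment of 2 mates of 150 bases counted over a read length of 75 bases would be worth 4 counts, so 1 fragment was taken as about 4 deposited counts. The FPKM values, per the file headers in that unit, cover the 32920 genes with a count in any library and were used for alternatives. Symbols came from a table of gene names that matched 60401 of the identifiers, of which 42020 have a symbol. Gene types, lengths and mitochondrial gene order came from GENCODE release 29, which holds 58394 of the identifiers.

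The estimated counts, already whole, were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by treatment and terms for cell line and treatment. This fit has 1 residual degree of freedom, and the 2 lines are the only replication of the treatment. Its p-values set the change common to both lines against their disagreement, moderated by dispersion borrowed from all genes (prior degrees of freedom 6.935). Genes passed at a Benjamini-Hochberg adjusted p below 0.05. The SE given beside a fitted log2 fold change is the fold change divided by the square root of F. No paired replicate numbers exist; the cell line is the block. Within a line no test is possible. There the log2 ratio of TMM-scaled CPM, counts relative to the scaled library total, with a pseudocount of 0.5 CPM was taken, and genes with a mean of at least 1 CPM over that line's 2 libraries were counted as higher or lower at 2-fold. Each ratio has an exact Clopper-Pearson 95% interval without the pseudocount. The design called for intervals on the counts as deposited; they were computed on counts divided by 4, a choice made after the values were seen, because deposited counts would make them too narrow if that reading of the counts is right. Intervals cover counting error only. A count of 0 was set at a limit of 3 fragments, or 12 deposited counts, per library when a fold was bounded.

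For 40 gene lists with 816 members, fixed before the data were examined, the median log2 ratio of the measured members (mean of at least 1 CPM over the 4 libraries, 15193 genes in all) was set among 10000 random lists of the same size, matched on mean expression in 20 bins. Members that passed the edgeR test were counted over all genes and adjusted over the list alone; the second count is not corrected for the number of lists. Agreement of the lines was described by Spearman's rho across genes and by overlaps beside those of independent lists.

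Genes were named by a rule fixed before the data were examined. For both lines it takes the 10 rising and 10 falling genes with a mean of at least 5 CPM that pass, filled up by unadjusted p. For each line it takes the 8 highest and 8 lowest ratios among genes with a symbol and at least 10 CPM. It takes the 5 genes each way with the largest difference between lines, up to 4 members per list by mean ratio plus the member with the smallest p, and EGFR, CDKN1A, TFRC, HMOX1, NQO1 and MKI67. A few genes that the rule takes are not reported here.

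Alternatives covered RLE size factors and library totals, other expression filters and pseudocounts, size rules of 1.5-fold and 4-fold, the FPKM table, a fit without the block, DESeq2 1.42.0, and limma 3.58.1 with voom on counts or with a trend on log2 FPKM. Added after the data were seen were edgeR on counts divided by 4, protein-coding genes only, counts without read-through genes (symbols joining 2 other genes of the table) and random lists from protein-coding genes. For some lists, chosen after their medians were seen, the trend on transcript length and GC content was removed by subtracting the median ratio of protein-coding genes alike in both. Python steps used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

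The edgeR step was tested on simulated counts for 21024 genes with the real means, library sizes and fitted trend of dispersion, and 50 changed genes at each fold. It recovered 10% of genes changed 2-fold, 86% at 4-fold, 94% at 8-fold and 98% at 16-fold, with 5 false calls. Each simulated change had the same fold in both lines, and dispersion followed the trend without a spread of its own per gene. Real genes differ in both respects, so these rates need not hold for the real data. The list percentile was tested on 15000 simulated genes: 5% of lists of 25 members without a shift lay outside the central 95%, and 39% of those shifted by 0.3 and 96% of those shifted by 0.6 on the log2 scale did.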

Results

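Gene expression was profiled in 4 libraries, 1 for each combination of 2 lung adenocarcinoma cell lines, A549 and HCC827, and 2 treatments. HCC827 is an EGFR-mutant line. Cells received DMSO or 20 µM hinokitiol for 24 h. The deposited counts summed to between 72146216 and 75099948 per library, and between 25309 and 26536 genes had a count. With 1 library per group, no ratio within a line has a replicate check, so those values compare libraries; higher and lower below refer to the hinokitiol library against the DMSO library of the same line. The 95% intervals cover counting error only and assume 4 deposited counts per fragment.

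The first comparison asked how far the lines differ, which also checks the labels. EGFR, the receptor whose gene is mutated in HCC827, stood at 265.7 and 274.9 CPM in the A549 libraries with DMSO and hinokitiol and at 5223 and 3891 CPM in the HCC827 libraries, a fitted log2 difference of 4.06 ± 0.35 (SE; edgeR adjusted p = 0.000186). The tight-junction genes CLDN4 and CLDN7 were also higher in HCC827, by 5.76 ± 0.49 and 6.89 ± 0.41 (SE; edgeR adjusted p = 0.000178 and 5.9e-05), as was the alveolar protease NAPSA by 5.61 ± 0.37 (SE; edgeR adjusted p = 6.4e-05). NQO1 and HMOX1, which encode a quinone reductase and haem oxygenase, were lower in HCC827, at −3.27 ± 0.352 and −2.502 ± 0.318 (SE; edgeR adjusted p = 0.00053 and 0.00115). CLDN2, another claudin, was lower at −5.17 ± 0.78 (SE), with an edgeR adjusted p of 0.00266. The line term takes both treatments together, so a response that differs between the lines enters it. CLDN2 stood at 958.2 CPM in A549 and 78.4 CPM in HCC827 with DMSO, and at 737.2 and 6.82 CPM with hinokitiol. CLDN4 stood at 7.20 and 234.2 CPM with DMSO, and at 14.8 and 1337 CPM with hinokitiol. In all, 5071 of 21024 genes passed edgeR's test of the line term, 2295 higher and 2776 lower in HCC827, with 2 libraries per line.

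In A549 cells, TXNIP and CBS had some of the highest ratios and CLSPN and FAM111B some of the lowest. TXNIP, an inhibitor of thioredoxin, was higher by 2.26 on the log2 scale (95% interval 2.08 to 2.55), and CBS, the first enzyme of transsulphuration, by 2.20 (95% interval 2.03 to 2.501). ABCG1, a cholesterol exporter, went from 2.04 to 22.3 CPM, the membrane mucin MUC16 from 12.4 to 62.1 CPM, and the long noncoding ADIRF-AS1 from 1.78 to 22.7 CPM. KLHL24, RASSF4 and AGAP2 had log2 ratios of 2.22, 2.22 and 2.40. CLSPN, the replication checkpoint adaptor claspin, was lower at −2.72 (95% interval −3.09 to −2.53) and FAM111B at −2.93 (95% interval −3.31 to −2.76). Other genes at the low end share reads with neighbours or copies and are uncertain. These are the read-through genes RPS10-NUDT3 (−2.84) and NME1-NME2 (1461 counts to no count, at least 136-fold lower), the multicopy NBPF19 (−3.38), the antisense gene TUBA1B-AS1 (−2.56) and the mitochondrial transfer RNA genes MT-TT (−3.26) and MT-TF (−2.88).

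By the 2-fold size rule, 806 of 14728 measured genes were higher in A549 cells and 601 lower, so that 57.3% of those past the rule were higher. This split was 73.2% with library totals as the scale, 44.6% with a pseudocount of 2 CPM and 36.0% among genes with a mean of at least 10 CPM. Scaling by library totals in place of TMM moves all ratios by 0.15 in A549 cells and by −0.126 in HCC827 cells.

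In HCC827 cells the log2 ratios of all measured genes had an SD of 0.908, against 0.623 in A549 cells. PIM1, a serine/threonine kinase gene induced by cytokines, went from 23.5 to 429.8 CPM (log2 ratio 4.17, 95% interval 4.06 to 4.33), and the cytokine gene TNF from 0.970 to 24.1 CPM (4.06, 95% interval 3.99 to 5.40). CYP1A1, the classical target of the aryl hydrocarbon receptor, went from 10.2 to 171.1 CPM (4.01, 95% interval 3.87 to 4.28), and the stress transcription factor ATF3 from 10.7 to 146.6 CPM (3.72, 95% interval 3.58 to 3.99). THEMIS2, SPRR2A and the histone gene H2BC21 had log2 ratios of 3.82, 3.81 and 3.74. On the low side stood NCOA5 at −4.46 (95% interval −5.29 to −4.27), SLC27A4, a fatty acid transport protein, at −3.76, and TIGAR, a regulator of glycolysis, at −3.63. CTPS1, which makes CTP, stood at −3.50 (95% interval −3.75 to −3.35), CLDN2 at −3.43, PIGW at −3.41, and MT-ND6, a mitochondrially encoded subunit of complex I, at −3.34. The MT-ND6 value is uncertain, because mitochondrial genes overlap or abut and whether counting used strand is not given. The read-through genes BIVM-ERCC5 (no count to 30.7 CPM, at least 203-fold higher) and BLOC1S5-TXNDC5 (35.6 CPM to no count, at least 208-fold lower) are uncertain because they share reads with their component genes.

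By the size rule, 1852 of 14527 measured genes were higher in HCC827 cells and 1538 lower, so that 54.6% of those past the rule were higher. This split was 43.5% with library totals as the scale and 45.9% with FPKM values.

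Changes common to both lines were tested with the lines as the replicates. TXNIP was higher in both lines, from 10.4 to 51.4 CPM in A549 and from 255.7 to 2517 CPM in HCC827 cells, a fitted log2 fold change of 2.81 ± 0.38 (SE). Its relative ARRDC4, another alpha-arrestin, had a fitted value of 2.12 ± 0.36 (SE). KLHL24 (2.37), the cyclin gene CCNG2 (1.86), the histone deacetylase gene HDAC5 (2.10), the TNF receptor gene TNFRSF1B (2.37) and ADIRF-AS1 (3.25) were also higher in both lines. The fatty acid receptor gene FFAR2 went from 2 to 50 deposited counts in A549 and from 1.83 to 27.4 CPM in HCC827 cells, so that its fitted value of 4.05 rests on a library near 0. CLSPN had a fitted value of −3.06 ± 0.37 (SE), the S-phase cyclin gene CCNE2 −2.58 ± 0.41 (SE), the cell-cycle phosphatase gene CDC25A −2.24 ± 0.35 (SE), and UHRF1, which guides maintenance DNA methylation, −2.01 ± 0.31 (SE). FAM111B had −2.61 ± 0.37 (SE). With edgeR's Benjamini-Hochberg adjustment none of these named genes passed; TXNIP had an adjusted p of 0.172, CLSPN 0.119 and CCNE2 0.254. All of them passed with DESeq2 and with edgeR on counts divided by 4. Uncertain for shared reads were BIVM-ERCC5, NBPF19 (−3.18), SENP3-EIF4A1 (−2.28), MT-TT (−3.74), MT-TF (−2.78) and the antisense gene ENSG00000272540 (−3.76).

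The gene that passed was ENSG00000286185, which has no symbol in the table of names. It had no count in either DMSO library and stood at 52.2 CPM in A549 and 69.5 CPM in HCC827 cells with hinokitiol, at least 302.6-fold and 459.4-fold higher (edgeR adjusted p = 0.0048). Thus 1 of 21024 genes passed edgeR, while 2273 had an unadjusted p below 0.05, against 1051 by chance. The count depended on the tool and the scale: 681 genes passed with DESeq2 and 846 with edgeR on counts divided by 4, of which 623 were shared, and 0 passed with library totals as the scale.

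Agreement of the lines was described across 15193 genes, which are not independent replicates. The log2 ratios had a Spearman's rho of 0.404, and 63.0% of genes had the same sign. Past the size rule in both lines were 317 higher genes, where independent lists of those lengths would share 90.0, and 214 lower genes, where they would share 61.1. Opposite calls were fewer than independent lists would give: 24 genes were higher in A549 and lower in HCC827 (79.7 for independent lists), and 21 the other way (69.0).

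**Figure D1:**
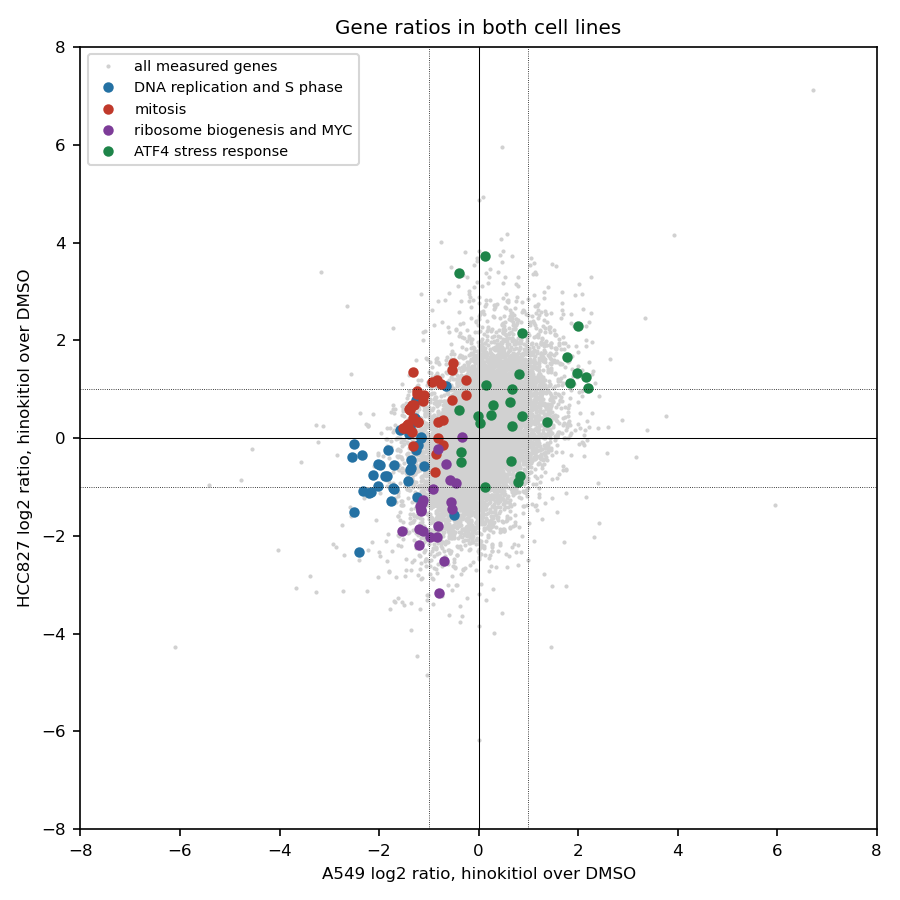
Log2 ratio of hinokitiol over DMSO for each measured gene (1 point per gene) in A549 cells on the x axis and HCC827 cells on the y axis, with dotted lines at 2-fold and 4 gene lists in colour. DNA replication genes lie low in both lines (medians −1.70 and −0.56), while mitosis genes lie low in A549 (−1.21) and above 0 in HCC827 cells (0.58).

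Genes furthest apart between the lines included CYP1A1, at −0.76 in A549 against 4.01 in HCC827 cells, and CCN1, a matricellular protein gene of the YAP response, at −1.16 against 2.95. ENSG00000288534 (−3.16 against 3.39), the second MATR3 identifier ENSG00000280987 (−1.73 against 2.24) and the read-through PPAN-P2RY11 (13.3 CPM to no count in A549, at least 86.0-fold lower, against −0.86) belonged to the same side; the MATR3 and PPAN-P2RY11 values are uncertain for shared reads. On the other side stood SLC27A4 (−0.38 against −3.76), NCOA5 (−1.23 against −4.46), CLDN2 (−0.38 against −3.43), ENSG00000266976 (0.29 against −3.09) and MIR34AHG, the host transcript of a microRNA under p53 control (0.32 against −4.00, 95% interval −12.6 to −4.74 without the pseudocount). With 1 library per group these differences could not be tested.

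Of the 37 gene lists with at least 3 measured members, 19 had a median outside the central 95% of matched random lists in A549 cells and 17 in HCC827 cells. For lists of randomly drawn genes 1.85 would fall outside. Members of a list can move together between any 2 cultures, and some lists share members. The percentiles therefore compare genes, and 1.85 is not the number expected without a treatment effect. In 11 lists both lines lay outside on the same side, 7 above and 4 below. With edgeR on the deposited counts no member of any list passed over all genes, so members said below to pass, rise or fall are those that edgeR called adjusted over the list alone. Other tools called members over all genes: DESeq2 called 15 of the S-phase list, 14 of ribosome biogenesis, 8 of ATF4 targets, 6 of heat shock and 6 of the mitochondrial mRNAs, and edgeR on counts divided by 4 called 20, 14, 9, 7 and 4.

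**Figure D2:**
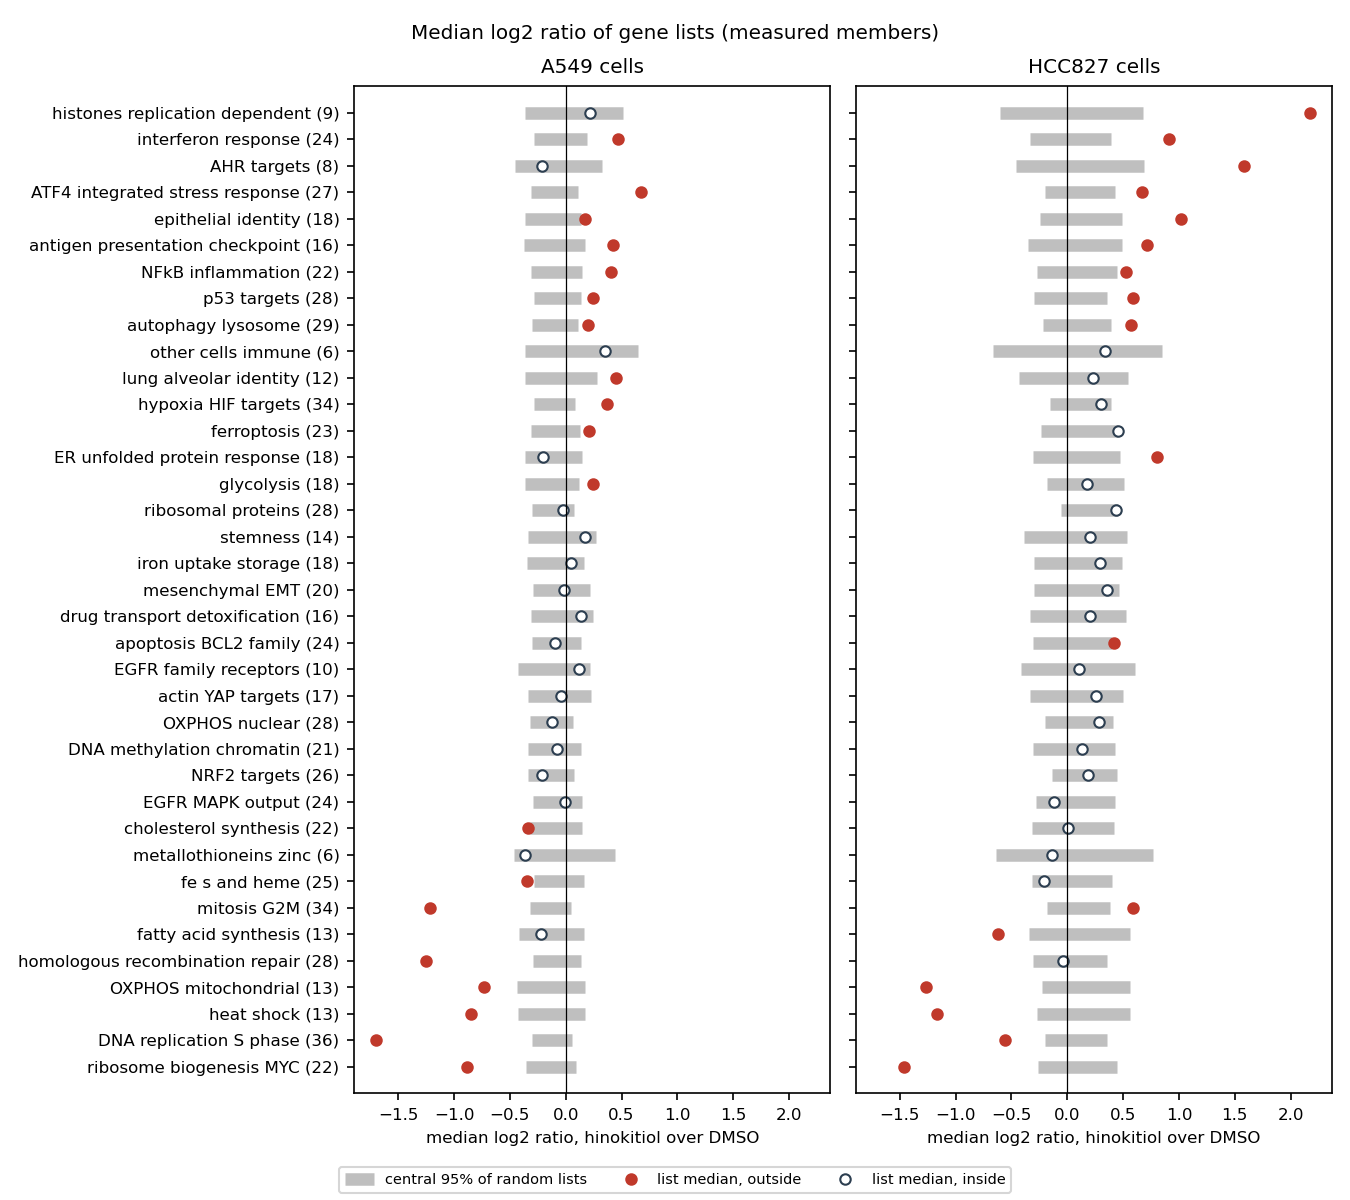
Median log2 ratio of hinokitiol over DMSO for each of 37 gene lists (x axis; measured members in brackets) in both lines, with grey bars for the central 95% of 10000 matched random lists and filled points outside them. Ribosome biogenesis and S-phase lists lie to the left in both lines, and histone genes lie at 0.21 in A549 and 2.18 in HCC827 cells.

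Genes of DNA replication and S phase were lower in both lines. Their median over 36 members was −1.70 in A549 cells and −0.56 in HCC827 cells, below all random lists in both, with 34 and 10 members at least 2-fold lower. Adjusted over the list alone, 23 fell and none rose. MCM10, an assembly factor of the replication fork, went from 82.3 to 14.0 CPM in A549 and from 28.0 to 9.42 CPM in HCC827 cells (edgeR adjusted p = 0.0109 over the list alone). The helicase subunit gene MCM6 and the flap endonuclease gene FEN1 had log2 ratios of −2.20 and −2.32 in A549 and −1.13 and −1.08 in HCC827 cells. Homologous recombination genes were lower in A549 (median −1.25, below all random lists) and near the middle in HCC827 cells (−0.03, percentile 34.8); 6 of 28 fell adjusted over the list alone, with XRCC2, XRCC3, BRCA2 and the checkpoint kinase gene ATR lower in both lines. In the list for DNA methylation and chromatin, whose medians were −0.08 and 0.13, UHRF1 and the maintenance methyltransferase gene DNMT1 (−1.30 and −1.16) fell over the list alone; EED had −1.13 and −0.58 and KDM5B 0.74 and 1.46.

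Mitosis genes moved apart. Their median over 34 members was −1.21 in A549 cells, below all random lists, and 0.58 in HCC827 cells, at percentile 99.95. In A549 cells 20 members were at least 2-fold lower, and in HCC827 cells 7 were at least 2-fold higher. None passed with edgeR over the list alone. KIF11, a spindle motor gene, had −1.50 and 0.21, CDCA8 −1.52 and 0.21, CDC20 −1.31 and −0.16, and ASPM −0.87 and −0.69. The proliferation marker MKI67 went from 689.8 to 261.8 CPM in A549 and from 326.5 to 371.9 CPM in HCC827 cells. Replication-dependent histone genes had a median of 0.21 in A549 (percentile 77.5) and 2.18 in HCC827 cells (above all random lists). With the trend on transcript length and GC content removed these were 0.39 and 2.19. The list was led by H2BC21, H2BC4 (3.11 in HCC827), H1-2 (2.45) and H2AC6 (2.25). None of 9 passed with edgeR over the list alone, while DESeq2 called 2 over all genes, H2AC6 and H2BC21. Because polyadenylated RNA was selected, these values describe polyadenylated histone transcripts only and need not follow histone expression as a whole.

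Ribosome biogenesis and MYC-linked genes were lower in both lines, with medians of −0.88 and −1.46, below all random lists; 17 of 22 fell adjusted over the list alone. NOP56, a nucleolar protein gene, went from 381.7 to 131.6 CPM in A549 and from 282.5 to 75.7 CPM in HCC827 cells (edgeR adjusted p = 0.00884 over the list alone). CAD, which starts pyrimidine synthesis, had log2 ratios of −0.79 and −3.18, UTP20 −1.19 and −2.20, and POLR1A, the largest subunit of RNA polymerase I, −0.70 and −2.51. Genes of ribosomal proteins themselves had medians of −0.03 and 0.43 (percentiles 80.2 and 96.1), the first changing sign to 0.13 with library totals; with the trend on transcript length and GC content removed they were 0.09 and 0.22, and percentiles were not recomputed. RPS9 had −0.04 and 0.78, RPL10 0.07 and 0.60 and RPLP0 0.14 and 0.50. Heat shock genes were lower, at −0.85 and −1.17 (−0.83 and −1.35 after the same removal), below all random lists, and 7 of 13 fell over the list alone: the chaperone genes HSP90AA1 (2610 to 901.0 CPM in A549 and 2182 to 895.7 CPM in HCC827), HSPA8, HSPH1 and DNAJA1 were among them.

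Mitochondrially encoded mRNAs were lower in both lines. Their share of all counts went from 7.82% to 5.48% in A549 (exact Clopper-Pearson 95% intervals 7.80% to 7.83% and 5.47% to 5.49%) and from 6.45% to 2.52% in HCC827 libraries (6.44% to 6.47% and 2.51% to 2.53%). The median over 13 mRNAs was −0.74 and −1.26, below all random lists, and 9 fell adjusted over the list alone. MT-CO2, a subunit of cytochrome c oxidase, had −1.74 and −2.32 (edgeR adjusted p = 0.00342 over the list alone), MT-ND5 −1.21 and −2.79, MT-ND3 −1.30 and −2.09, and MT-ND6 −1.70 and −3.34. Neighbouring mitochondrial genes overlap or abut, so single values are uncertain. Nuclear genes of oxidative phosphorylation had medians of −0.13 and 0.29 (percentiles 48.4 and 86.3), the first changing sign to 0.03 with library totals and both moving, to −0.01 and 0.14, once the trend on transcript length and GC content was removed, with NDUFA9 at −0.53 and −0.48, COX5B at 0.21 and 0.89, COX6C at −0.03 and 0.79 and SDHD at 0.06 and 0.72; none passed with edgeR.

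**Figure D3:**
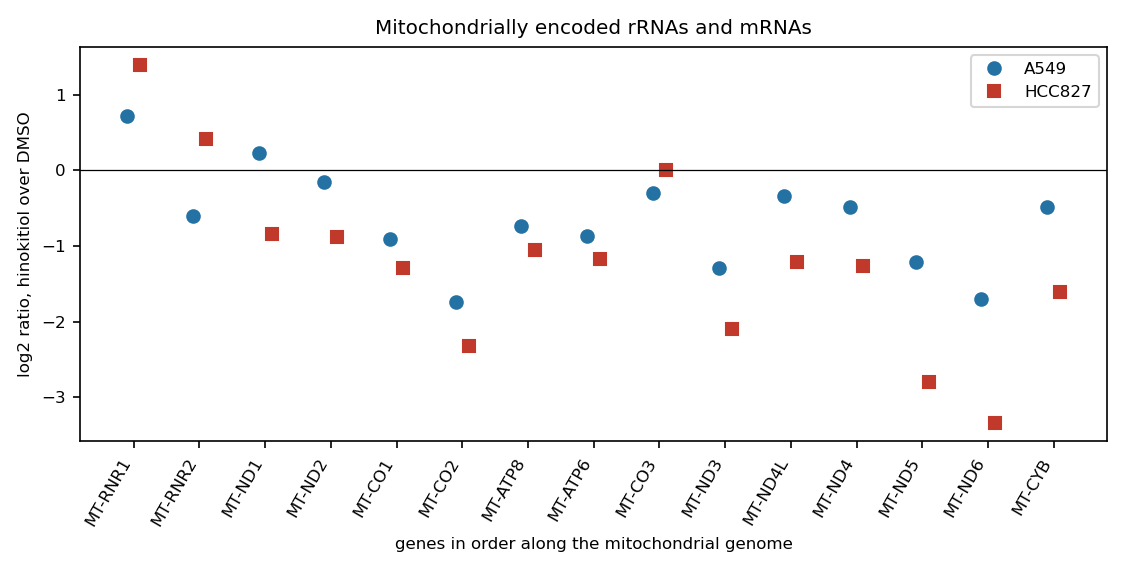
Log2 ratio of hinokitiol over DMSO (y axis) for the mitochondrial rRNAs and 13 mRNAs in their order along the mitochondrial genome (x axis), with 1 library per treatment in each line. MT-RNR1 lies above 0 in both lines (0.72 and 1.39), while MT-CO2 and MT-ND6 lie below −1.6.

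Targets of ATF4 and of p53 were higher in both lines. Those of ATF4, the transcription factor of the integrated stress response, had a median of 0.67 in each line (above all random lists in A549, percentile 99.98 in HCC827), and 8 of 27 rose adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, went from 37.2 to 127.9 CPM in A549 and from 41.3 to 130.8 CPM in HCC827 cells (edgeR adjusted p = 0.00711 over the list alone). CHAC1, a glutathione-degrading enzyme gene, had 2.16 and 1.24 and NUPR1 2.00 and 2.28, both also past the threshold over the list alone, while ATF3 had 0.13 and 3.72. Genes of the unfolded protein response of the endoplasmic reticulum had medians of −0.20 (percentile 23.9) and 0.80 (above all random lists), with HERPUD1 at 0.50 and 2.17, DNAJB9 at 0.55 and 2.02, CRELD1 at 0.38 and 1.59 and XBP1 at 0.58 and 1.16; none passed with edgeR, while DESeq2 called HERPUD1 over all genes. The p53 list had medians of 0.25 and 0.59 (percentiles 99.9 and 99.98), and GDF15 (1.25 and 2.59), BBC3 (1.31 and 2.42) and TP53INP1 (1.82 and 1.57) rose over the list alone, while TIGAR had −0.60 and −3.63. CDKN1A, the p53-induced cell-cycle inhibitor, had 0.85 and 0.60. In the BCL2-family list, with medians of −0.09 (percentile 48.7) and 0.42 (percentile 98.1), BBC3 passed; PMAIP1 had 0.23 and 1.82, BMF 1.79 and 0.61 and BIRC3 0.30 and 1.47. Autophagy and lysosome genes had medians of 0.20 and 0.57 (percentiles 99.8 and 99.9), with GABARAPL1 at 0.78 and 1.94, WIPI1 at 1.53 and 1.08, NBR1 at 0.77 and 1.64 and RRAGD at 0.78 and 1.27; none passed with edgeR, while DESeq2 called GABARAPL1, WIPI1 and NBR1 over all genes.

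Genes of iron handling were examined because hinokitiol binds iron. TFRC, the transferrin receptor, was higher at 0.86 (95% interval 0.82 to 0.91) in A549 and 0.48 (95% interval 0.45 to 0.52) in HCC827 cells, and the ferritin heavy chain gene FTH1 at 0.42 and 1.81. The iron importer gene SLC11A2 had 0.52 and 1.74, the exporter gene SLC40A1 1.24 and 0.72, and the mitochondrial iron importer gene SLC25A37 0.56 and 0.92. The 18 measured members had medians of 0.05 and 0.30, inside the random range (percentiles 86.9 and 81.5), and none passed with edgeR over the list alone. Iron-sulphur cluster and haem genes had medians of −0.35 (percentile 0.66) and −0.21 (percentile 7.57), with IBA57 at −0.54 and −2.04 and LYRM4 at −0.29 and −1.19; none passed with edgeR. Targets of the hypoxia factor HIF had medians of 0.37 (above all random lists) and 0.30 (percentile 89.2), and ALDOC, an aldolase, rose over the list alone at 1.87 and 1.67. NDRG1 had 1.10 and 1.46, MXI1 1.26 and 0.84 and LOX 0.49 and 1.83. The A549 ratio of LOX rests on 43 and 83 deposited counts (95% interval −0.35 to 1.97). Glycolysis genes, which include ALDOC, had medians of 0.25 (percentile 99.9) and 0.17 (percentile 45.0), with GAPDH at 0.27 and 0.94, ALDOA at 0.24 and 0.84 and the lactate exporter gene SLC16A3 at 1.43 and 0.05. In the ferroptosis list (0.21 and 0.45, percentiles 99.7 and 97.3), the polyamine acetyltransferase gene SAT1 rose over the list alone at 1.31 and 2.99, and the lipoxygenase gene ALOX5 had 1.68 and 0.75. NRF2 targets had medians of −0.21 and 0.19 (percentiles 18.1 and 51.0), with HMOX1 at −0.67 and −0.46, GCLM at −0.79 and −0.52, NQO1 at 0.13 and 0.78, UGDH at −0.16 and 1.85 and ABCC2 at −0.29 and −1.28; none passed with edgeR. Metallothionein and zinc genes had medians of −0.37 and −0.14 over 6 members (percentiles 6.09 and 26.7), with MT1F at −0.19 and 2.04, MT1X at −0.56 and −0.97, SLC39A10 at −0.40 and −0.72 and SLC30A1 at −0.39 and −0.14.

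Interferon, NF-κB and antigen presentation genes were higher in both lines. The interferon list had medians of 0.47 and 0.91, both at percentile 99.99 (0.53 and 0.645 with the trend on transcript length and GC content removed), and IRF9, a subunit of the interferon-activated complex, rose over the list alone at 1.45 and 1.87; IFIT1 had 0.98 and 2.85, IFIT2 0.86 and 2.00 and STAT2 0.62 and 1.80. NF-κB and inflammation genes had medians of 0.40 (above all random lists) and 0.53 (percentile 99.2), where IL1B rose over the list alone at 1.27 and 2.04; IL6 had 0.67 and 3.72, CXCL8 0.44 and 2.07 and TNF 0.44 and 4.06. Antigen presentation genes had medians of 0.43 and 0.72 (percentiles 99.97 and 99.9), with HLA-E at 0.84 and 1.87, HLA-B at 0.81 and 1.65, B2M at 0.35 and 1.27 and TAP2 at −0.35 and −1.21; none of 16 passed with edgeR, while DESeq2 called HLA-E and HLA-B over all genes, and genes of the HLA family share similar sequence. Of 12 markers of immune cells 6 were measured, with a median of 0.34 in HCC827 cells (percentile 76.5); CD68 had 0.55 and 1.57, CD14 1.44 and 0.19 and ITGAM 0.75 and 0.64, and HLA-DRA had 0.49 in HCC827 cells. In A549 cells HLA-DRA had 0 and 4 deposited counts, too few for a ratio, and no list median is given. Of the fibroblast, endothelial and erythroid markers 1, 2 and 0 were measured.

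The median of epithelial genes was above 0 in both lines, at 0.17 in A549 (percentile 98.8) and 1.01 in HCC827 cells (above all random lists). In A549 cells 11 members lay above 0 and 7 below, and 1 was at least 2-fold higher. Adjusted over the list alone 4 of 18 rose, among them CLDN4 (234.2 to 1337 CPM in HCC827 cells), CLDN3 (20.9 to 79.4 CPM) and CLDN7 (0.81 and 1.58); OVOL1 had 0.12 and 2.53. Mesenchymal genes had medians of −0.01 and 0.36 (percentiles 58.1 and 91.3), with FN1 at 1.16 and 0.87, SNAI1 at −0.17 and 2.89 and CCN2 at −0.12 and 2.83. The actin and YAP list stood at −0.04 and 0.26 (percentiles 51.5 and 76.4), with AMOTL2 at 0.05 and 2.59, LATS2 at 0.03 and 1.82 and ACTA2 at 1.23 and 1.04. Alveolar genes had medians of 0.45 (percentile 99.7) and 0.23 (percentile 73.5), with MUC1 at 0.83 and 1.16, SLC34A2 at 0.61 and 0.94, NAPSA at 0.57 and 0.81 and ABCA3 at 0.30 and −1.17. Stemness genes stood at 0.18 and 0.21 (percentiles 92.2 and 70.3), with NOTCH3 at 1.44 and 0.52, SOX2 at 0.67 and 0.63, HES1 at 0.36 and 1.04 and ABCG2 at −0.48 and −1.92. None passed with edgeR in these last 4 lists, while over all genes DESeq2 called FN1 and edgeR on counts divided by 4 called SNAI1 and AMOTL2.

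Outputs of EGFR and MAPK signalling had medians of −0.01 and −0.12 (percentiles 69.9 and 13.5). FOSL1, an AP-1 subunit gene, fell over the list alone at −1.32 and −1.55, and CCND1, the G1 cyclin gene, had −0.98 and −1.07, EGR1 −0.28 and −2.19 and DUSP5 0.62 and 1.41. EGFR itself had 0.05 in A549 and −0.43 (95% interval −0.44 to −0.41) in HCC827 cells. A list of growth factor receptors and kinases stood at 0.12 and 0.11 (percentiles 91.6 and 47.8), with ERBB3 at 1.44 and 0.78, ERBB2 at 0.18 and 0.37, FGFR1 at −1.12 and 0.21 and BRAF at 0.25 and 1.13. Targets of the aryl hydrocarbon receptor had medians of −0.21 in A549 (percentile 20.9) and 1.58 in HCC827 cells (above all random lists), with CYP1B1 at −0.03 and 3.19, TIPARP at −0.39 and 2.59 and UGT1A6, whose exons are shared with other genes of its locus, at −3.27 in A549 cells. Fatty acid synthesis genes stood at −0.22 (percentile 24.9) and −0.62 (percentile 0.17), with FASN at −0.84 and −2.37, ACACA at −0.29 and −1.96, ELOVL6 at −0.12 and −1.51 and FADS1 at −0.69 and −1.13. Cholesterol synthesis genes stood at −0.34 (percentile 1.81) and 0.00 (percentile 36.8), with INSIG1 at −0.33 and 1.87, STARD4 at 0.27 and 1.39, DHCR7 at −0.61 and −0.69 and HSD17B7 at 0.41 and 0.96. Drug transport and detoxification genes stood at 0.13 and 0.20 (percentiles 87.9 and 65.1), with CYP24A1 at 0.68 and 0.93 and CYP3A5 at 0.69 and 1.41. None passed with edgeR in the receptor and kinase, aryl hydrocarbon, fatty acid, cholesterol and drug lists, while over all genes DESeq2 called ERBB3 and FASN, and edgeR on counts divided by 4 called ERBB3, FASN, ACACA, CYP1A1, CYP1B1 and UGT1A6.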

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

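The test of library scaling for mitosis genes was chosen after its result was seen. Each result below moved in opposite directions in the 2 cell lines, with 1 library per group, and the difference itself was not tested. The median of the mitosis genes lay 1.72 higher on the log2 scale in HCC827 than in A549 cells, as the median of the differences per gene. CCN1 differed by 4.11, ENSG00000288534 by 6.56, the second MATR3 identifier ENSG00000280987 by 3.97 and the antisense gene TUBA1B-AS1 by 3.87, each at least 2-fold lower in A549 and at least 2-fold higher in HCC827 cells.

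The opposite move of mitosis genes, beside S-phase genes that were lower in both lines, was weighed against technical explanations. After the trend on transcript length and GC content was removed the median went from 0.584 to 0.442 in HCC827 and from −1.21 to −1.06 in A549 cells, which argues against such a bias as the whole cause. Over 3 scalings the lowest HCC827 median was 0.455 and the highest A549 median −1.06, so the choice among them did not turn either sign. These scalings move all ratios by at most 0.15 in size, so this test could hardly have come out otherwise. Of 620 genes at least 16-fold apart between the DMSO libraries, 98.55% in the HCC827 and 99.8% in the A549 hinokitiol library lay closer to the DMSO library of the same line, which argues against a wrong line label. The cause stays open: no biological explanation was tested, and with 1 library per group variation between cultures is not excluded.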

How the results depend on the processing

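The alternatives with counts divided by 4, with protein-coding genes or without read-through genes were chosen after the data were seen. Of 368 list medians under alternatives 354 stayed within the interval of their median, 14 moved beyond it, and none that lay outside the random range changed sign. Of 1808 values of named genes per line 1287 stayed within their counting interval and 521 moved beyond it, none past the size rule changing sign. The count of genes different between the lines ranged from 3771 to 7264. The count of genes changed in both lines, 1 in edgeR, was 14 with RLE size factors, 0 with library totals, 5 with a mean of at least 5 CPM, 0 with no replicate block (the other factor left out), 681 with DESeq2, which gave 15956 genes no adjusted p, 0 with limma on log2(FPKM + 1) and 0 on log2(FPKM + 0.1), and 846 with edgeR on counts divided by 4; the cause was not tested. Unadjusted p-values below 0.05 numbered 2140 with library totals, 321 with no block, and 2299 and 2648 in the FPKM fits. Per line, a pseudocount of 2 CPM gave 374 higher genes in A549 cells. A mean of at least 10 CPM, which tests fewer genes, gave 256 higher in A549, and 1071 higher and 962 lower in HCC827 cells. FPKM values gave 486 higher and 334 lower in A549 and 1104 higher and 1301 lower in HCC827 cells. A 1.5-fold rule gave 2155 higher and 2026 lower in A549 and 3708 and 3055 in HCC827 cells; a 4-fold rule gave 61 and 53, and 291 and 242. Genes higher in both lines numbered 137 with a pseudocount of 2 CPM, 168 with FPKM values (126 lower in both) and 141 with a mean of at least 10 CPM, and rho was 0.442 with FPKM values and 0.462 with at least 10 CPM. No replicate could be left out, since without a line no residual degree of freedom remains. Depth limits genes near 12 counts, and ratios against no count are bounds.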

Other observations

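The tests of read-through genes, of ENSG00000286185 with NBPF19, of the mitochondrial RNAs and of immune markers were chosen after related values were seen; the test of gene length was not.

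In HCC827 cells the mitochondrial ribosomal RNAs did not follow the mRNAs. The ribosomal RNA MT-RNR1 was higher in both lines (0.72 in A549 and 1.39 in HCC827 cells), and MT-RNR2 had −0.60 and 0.41. All 21 measured mitochondrial transfer RNA genes were below 0 in both lines, with medians of −1.08 and −1.67, though such short RNAs are poorly captured by this kind of library and their reads can come from adjoining transcripts. A smaller share of mitochondrial RNA of every kind would lower rRNAs and mRNAs alike. In HCC827 cells the rRNA median lay 2.163 above the mRNA median, more than the interquartile range of the mRNAs of 1.04. This argues against such a smaller share among the captured transcripts of that line. In A549 cells the gap of 0.798 was within the interquartile range of 0.881, so this explanation stays open in that line. Because polyadenylated RNA was selected, the rRNA values describe captured rRNA only and need not follow mitochondrial RNA as a whole. Over 3 scalings and both lines the highest mRNA median was −0.583, so the choice among them did not turn the sign. These scalings move all ratios by at most 0.15 in size, so this test could hardly have come out otherwise. It does not decide on scaling beyond these 3 choices. A decline with distance from the heavy-strand promoter stays open: across 14 genes, which are not independent replicates, Spearman's rho with position was −0.679 in HCC827 (two-sided permutation p = 0.0098, 0.0196 adjusted over both lines) and −0.327 in A549 cells (permutation p = 0.252, also after adjustment). The 14 genes include MT-RNR1 and MT-RNR2, which come first in the order and in HCC827 cells lay above all mRNAs. The value of rho therefore does not separate a decline along the mRNAs from the difference between rRNAs and mRNAs.

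Several loci switched between no count and a clear level. Read-through genes were changed at least 4-fold more often than other genes: 15.5% of 58 against 0.716% in A549 (Fisher's exact p = 5.62e-10) and 21.1% of 57 against 3.6% in HCC827 cells (Fisher's exact p = 8.24e-07), or 1.12e-09 and 8.24e-07 adjusted over both lines by Benjamini-Hochberg, where genes share reads and the p-values are therefore descriptive. Against other genes of the same mean CPM the smaller of the 2 ratios was 4.51, consistent with unstable assignment of reads among overlapping genes, although a change in read-through transcription would give the same values. Summed with their component genes, 21 such values had a median absolute log2 ratio of 0.451, but the read-through gene made up a median of 10.2% of the sum at most, so this test could hardly have come out otherwise. ENSG00000286185 summed with NBPF19 changed by at most 0.118 in size, which would fit reads passing from one gene to the other, but the pair was picked for this match and 99 genes lost a like number of counts (within 30%) in both lines, so a passage of reads and an independent change cannot be told apart.

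A hypothesis that long genes were lower with hinokitiol, as impaired transcript elongation may give, was not borne out: across 13171 protein-coding genes the lower Spearman's rho of the 2 lines between log2 ratio and gene length was −0.031, and the other was 0.069. A hypothesis that interferon and MHC genes were higher because of RNA from immune cells was examined with 5 markers. Such cells would bring their own abundant transcripts along with B2M, which went from 245.3 to 313.0 CPM in A549 and from 345.1 to 834.5 CPM in HCC827 cells. PTPRC, CD3E, MS4A1 and LYZ had no count in either hinokitiol library and CD3D at most 0.057 CPM; set at the limit of 3 fragments, these markers come to at most 0.228% of the rise of B2M in either line. The 5 markers and this measure were chosen with their low levels known, so this test could hardly have come out otherwise. It shows only that these 5 transcripts were near absent from the hinokitiol libraries. CD68, CD14 and ITGAM, which had counts with DMSO as well, do not decide the question.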
